A study of Rattus norvegicus with 9 samples.

How the data were processed

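The samples were retinal ganglion cells of Sprague Dawley rats at postnatal day 4, the projection neurons of the retina whose axons form the optic nerve. Per the labels' protocols, the cells were purified by immunopanning, which captures cells on antibody-coated dishes. They were electroporated with mCherry as the control, with wild-type Set-β or with myr-Set-β, each together with a green fluorescent protein plasmid. Fluorescent cells were sorted the next day and cultured further on laminin, and RNA was taken 3 days after transfection. Each of the 3 groups had 3 arrays, which the titles call biological replicates. The labels do not say whether a replicate was a separate litter or culture, so the p-values measure the spread between these arrays, which may be technical.

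Per the series' design text, RNA was amplified with a whole-transcriptome kit for small inputs, labelled with biotin and hybridised to Affymetrix Rat Gene arrays. The submitters' processing notes name Affymetrix Expression Console and RMA, without versions. RMA corrects background, normalizes between arrays and summarises the probes of a transcript cluster. Per the design text the authors then normalized the values to the median of each sample. The deposited table holds intensity values on a linear scale for 36685 transcript clusters, and the median of each of the 9 arrays was 100. This step fixes the middle of each array and leaves its spread free, so that arrays with a narrower signal range show lower values for abundant transcripts. Arrays carry no read depth, and their number limits the precision.

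A platform annotation table paired 18511 clusters with 1 gene symbol, 575 with several and 17599 with none, and no gene was named from a cluster with several. Of the annotated gene identifiers, 18394 matched the RefSeq gene table of assembly GRCr8, which served for names only. The genome build of the array design is not given in the sources used here, and no coordinates are printed. No cluster carried the symbol Set. Control clusters could not be separated with the tables used here and stayed in. In 752 clusters the values were identical to those of another cluster.

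The intensities were log2-transformed in R 4.3.3. All 9 arrays were fitted in 1 model of group means with limma 3.58.1 (lmFit and eBayes), two-sided, with 6 residual and 2.82 prior degrees of freedom. Clusters whose mean log2 value was below the median of all cluster means (6.65) were left out. This left 18343 clusters, of which 10714 carried 1 symbol. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Differences are log2 values with the standard error of the fit, and group levels are mean ± SD of log2 intensity. The fit was tested on simulated data with the spread of these arrays, 18343 clusters and 100 changed clusters of each size. The noise was independent between clusters, so the false calls do not cover deviations that genes share on the real arrays. For wt_Set against mCherry, 12% of the changes of 1 log2 unit and 73% of those of 2 were recovered, with 2 false calls. For myr_Set against mCherry these shares were 16% and 72% with 4 false calls, and for myr_Set against wt_Set 17% and 77% with 7.

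Before the data were examined, 30 gene lists were fixed. They held markers of ganglion cells and of other cell classes (amacrine and horizontal, photoreceptor and bipolar, glial, microglial and macrophage, and endothelial, mural and fibroblast), and genes of Set with protein phosphatase 2A and of histone acetylation. Lists on neurons held Krüppel-like factors, regeneration-associated genes, axon guidance, growth inhibition, cytoskeleton, synapse, voltage-gated channels, immediate early genes and growth factor signalling. The others held stress and apoptosis, p53 targets, heat shock and unfolded protein response, interferon, NF-kB and cytokines, cell cycle, integrins and matrix, sterol synthesis, glycolysis and hypoxia, splicing, respiratory chain, ribosomal proteins and histones. Each gene was represented by its cluster of highest mean, which gave 10518 genes. Lists were tested with camera at a preset inter-gene correlation of 0.01, two-sided, with adjustment over 90 tests. Camera sets a list against all other genes. An estimated correlation and fry, which tests whether a list moves on balance one way, were alternatives. Each list was also set against 10000 random lists matched on mean level, a comparison added after seeing the data. Their genes were drawn independently of each other, so the range does not cover movements that genes share. In simulated data with 1 list shifted by -0.5 in wt_Set against mCherry over 10518 genes, that list was called and 0 of 88 other tests were. The noise was again independent between genes. The simulation therefore cannot show how often camera calls lists falsely where genes are correlated.

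The rule for named genes was also fixed beforehand. It took, per comparison and direction, up to 12 single-symbol genes past the threshold whose 3 arrays of a group all lay above the 3 of the other. Missing places were filled by the smallest unadjusted p under 0.01 with the same separation. Symbols of unnamed loci, microRNAs, small nucleolar RNAs and vomeronasal receptors and the older-style symbols of olfactory receptors were left out. The rule added Set, for each list past camera's threshold up to 2 members per direction with the smallest p, for other lists at most 1, and the most abundant marker of each cell class. Not every list member that the rule allowed is named, and which of them are was chosen after their values were seen. Setsip, whose older names in the RefSeq table include Set, as do those of Setl1, stands for Set, a choice made after the annotation was seen.

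Alternatives fixed beforehand were no level filter or a filter at the 75th percentile, quantile normalization, recentred medians, eBayes with trend and robust settings, array weights, a replicate block, fits of only the groups compared, single-symbol clusters only, an adjusted p under 0.1 and the omission of each array in turn. Cyclic loess normalization, gene-by-gene array weights, a term for replicate 1 against replicates 2 and 3, and replicates 2 and 3 alone were added after seeing the data.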

Results

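Gene expression was measured on 9 arrays from rat retinal ganglion cells 3 days after transfection. There were 3 arrays labelled mCherry, the control, 3 labelled wt_Set, with wild-type Set-β, and 3 labelled myr_Set, with myr-Set-β. Set is a nuclear histone chaperone and an inhibitor of protein phosphatase 2A, and myristoylation is a lipid modification that places proteins at membranes. The comparisons ask how either form of Set-β alters gene expression in these neurons, and whether the forms differ. Stmn2, a microtubule regulator of growing neurites, was the most abundant ganglion cell marker, with a log2 intensity of 11.76 ± 0.43 (SD, n = 3) in mCherry, 11.13 ± 0.53 in wt_Set and 11.34 ± 0.42 in myr_Set.

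The arrays differed in signal range. The distance from the 10th to the 90th percentile of log2 intensity was 4.45 ± 0.146 (SD, n = 3) in mCherry, 4.16 ± 0.0471 in wt_Set and 4.16 ± 0.318 in myr_Set, where replicate 1 had 3.82 and replicate 3 had 4.46. By exact permutation test, two-sided, p was 0.1 for wt_Set against mCherry, the smallest value that 3 against 3 allows, 0.2 for myr_Set against mCherry and 1 between the forms of Set. In the most abundant decile of clusters the median difference from mCherry was -0.43 in wt_Set and -0.47 in myr_Set. These values were -0.11 and -0.18 after quantile normalization and -0.08 and -0.04 after cyclic loess. The median difference of all tested genes was -0.29 in wt_Set, -0.26 in myr_Set and 0.01 between the forms of Set, -0.11, -0.12 and -0.01 with quantile normalization, and -0.12, -0.09 and 0.01 with cyclic loess. Gene lists past camera's threshold are therefore also given relative to the median of all genes.

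**Figure D1:**
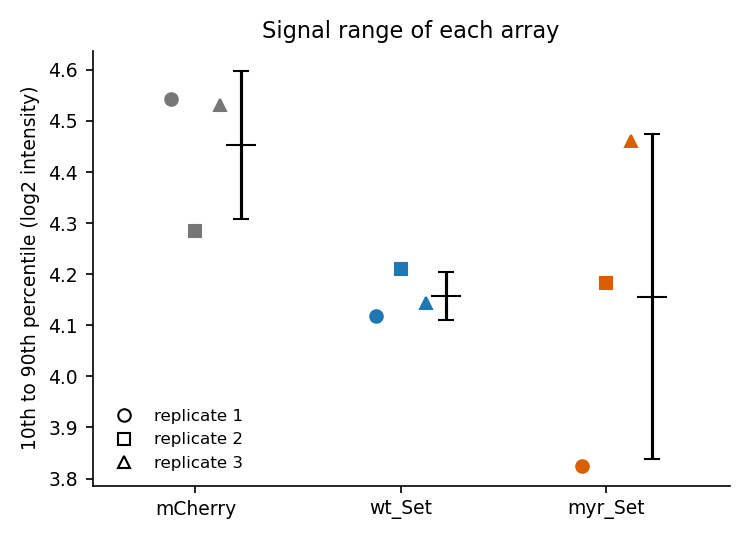
Signal range of each array (y axis, distance between the 10th and 90th percentile in log2 intensity) by group, with symbols for the replicate number and bars for mean ± SD (n = 3). The mCherry arrays lay between 4.29 and 4.54, the wt_Set arrays between 4.12 and 4.21, and the myr_Set arrays between 3.82 and 4.46.

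**Figure D2:**
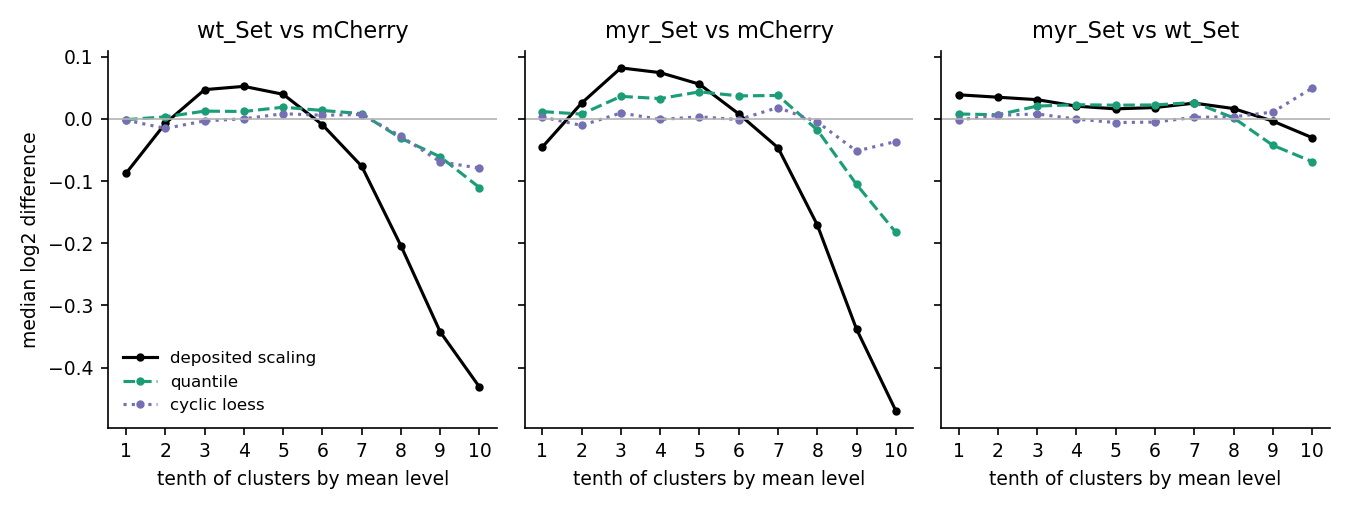
Median log2 difference (y axis) in each decile of the 36685 clusters by mean level (x axis, 1 is the dimmest), with lines for the deposited scaling, quantile and cyclic loess normalization. In the most abundant decile the deposited scaling gave -0.43 in wt_Set and -0.47 in myr_Set against mCherry, and -0.03 between myr_Set and wt_Set.

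The transfected gene could be followed only in part. Setsip (cluster 17731176), which stands for Set here, had a log2 intensity of 10.76 ± 0.08 (SD, n = 3) in mCherry and 10.10 ± 0.20 in arrays labelled wt_Set. The differences from mCherry in wt_Set and myr_Set, -0.65 ± 0.31 (SE) and -0.76 ± 0.31, had a limma adjusted p of 0.447 in both comparisons, and the difference between the Set groups was -0.10 ± 0.31. Leaving out 1 array moved the difference of myr_Set from mCherry by over 1.5 times (Setl2 0.28 without mCherry replicate 2, Setl2 0.07 without mCherry replicate 3, and Setsip -0.41 without myr_Set replicate 1), and also that between the Set groups (Setsip 0.015 without wt_Set replicate 1, Setsip -0.17 without wt_Set replicate 2, Setsip -0.16 without wt_Set replicate 3, Setsip 0.25 without myr_Set replicate 1, and Setsip -0.44 without myr_Set replicate 3). Among the 200 genes nearest in level the 3 differences lay at percentiles 30.5, 21 and 37. The pseudogene Setl2 had 7.94 ± 0.22 in mCherry, 7.31 ± 0.35 in wt_Set and 8.11 ± 0.07 in myr_Set, and Setl1, below the level filter, had 3.15 ± 0.12, 3.07 ± 0.02 and 3.05 ± 0.11. The species of the construct and whether any probe detects it are not given in the sources used here. These values therefore do not check the labels, and groups are named as labelled.

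The comparison of wt_Set with mCherry asks what wild-type Set-β alters. Aifm1, a mitochondrial flavoprotein that also acts in cell death, had the smallest p among the selected genes and was lower in wt_Set, with 6.91 ± 0.03 against 7.65 ± 0.09 (SD, n = 3) in mCherry. Other lower genes were Isg20l2, an exonuclease of ribosomal RNA maturation (-1.02 ± 0.21 SE), Zmat2, a spliceosome protein (-1.06 ± 0.22), Med6 of the Mediator complex (-0.76 ± 0.17), Gemin2 of the SMN complex (-0.91 ± 0.22) and Fabp3, a fatty acid carrier (-0.91 ± 0.21). Higher in wt_Set were Cx3cr1, the fractalkine receptor of microglia (7.29 ± 0.15 against 6.56 ± 0.30), and RT1-O1, a class I histocompatibility gene (7.34 ± 0.58 against 6.07 ± 0.39). The odorant receptor genes Or8a1b (8.15 ± 0.55 against 5.78 ± 0.14), Or52n4d (9.53 ± 0.31 against 8.28 ± 0.66) and Or52r1c (6.94 ± 0.07 against 6.02 ± 0.44) were also higher. The median signal of odorant receptors, used below as a mark of background, was 6.81, 7.30 and 7.09 on the mCherry arrays and 7.29 to 7.41 in wt_Set. Only receptors past the level filter enter this median, so it may overstate background. Cx3cr1 and RT1-O1 were below this median on every mCherry array, and Aifm1, Isg20l2 (cluster 17881142), Med6 and Gemin2 on every wt_Set array. The sizes of these differences are therefore uncertain. No cluster passed limma's adjusted p of 0.05, and the smallest value, 0.447, was that of each gene named so far in this comparison.

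The other genes that the rule selected had the same adjusted p. On the lower side these were Glt8d1, a glycosyltransferase (-0.82 ± 0.19), Ccdc82 (-1.02 ± 0.24), Tmem177 (-0.74 ± 0.18), Pdrg1 (-0.76 ± 0.18), Cxhxorf38 (-0.88 ± 0.21) and Zfp35, a zinc finger gene (-0.78 ± 0.19). On the higher side they were Tmem258l2 (0.87 ± 0.19), Gpd1l3 (0.65 ± 0.17), Rflna (0.54 ± 0.16), Obp1f, an odorant binding protein (cluster 17877478, 0.88 ± 0.26), Tmem92 (0.86 ± 0.26) and the odorant receptors Or10ak7 (0.66 ± 0.20) and Or5af1c (0.97 ± 0.29). The other cluster of Obp1f went the other way (-0.21 ± 0.27), and those of Isg20l2 and Tmem92, the latter below the level filter, had -0.68 ± 0.30 and 0.68 ± 0.17. Glt8d1, Ccdc82, Tmem177, Cxhxorf38 and Zfp35 were below the odorant receptor median on every wt_Set array, and Gpd1l3 on every mCherry array. At an unadjusted p under 0.05 there were 1865 clusters, 557 higher and 1308 lower, where 917 would be expected by chance. The share of higher clusters, 29.9%, was 62.1% with quantile normalization and 54.5% with cyclic loess. The arrays of wt_Set and mCherry did not overlap in 33.7% of clusters, against 10% by chance. The 10% holds for arrays that differ only by chance, whereas the signal ranges of these groups did not overlap either. This share was computed with the deposited scaling only, so an effect of scaling is not separated. The 1865 clusters became 880 without mCherry replicate 1, 992 without mCherry replicate 3, 1052 and 914 without wt_Set replicates 2 and 3, and 3862 and 3222 without myr_Set replicates 1 and 3, which enter the estimate of spread. They became 4262 in a fit of only these 2 groups, 4688 with gene-by-gene and 6279 with planned array weights, and 3043 with no level filter, 885 with the filter at the 75th percentile and 1159 with single-symbol clusters only, which change the number tested.

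Of the 30 gene lists, 9 passed camera's adjusted p of 0.05 in wt_Set, 5 of them below and 4 above the other genes. With an estimated correlation none passed (adjusted p = 0.969 for each), nor with fry (lowest adjusted p = 0.375), and 0 members passed when adjusted over the list alone. Nuclear respiratory chain genes had a median difference of -0.52, -0.24 relative to all genes, with 80 of 83 lower than in mCherry (adjusted p = 0.00356). Among them Ndufs4, a complex I subunit, had 8.76 ± 0.42 against 9.66 ± 0.17 (SD, n = 3). Splicing factors had -0.54, -0.26 relative to all genes, with 46 of 46 lower (adjusted p = 0.00916), among them the neuronal splicing factor Nova1 (-0.64 ± 0.19 SE) and Elavl1 (-0.64 ± 0.24). Cytoskeleton genes had -0.48, -0.20 relative to all genes, with 47 of 47 lower (adjusted p = 0.00513), with the tubulin Tuba4a at -0.99 ± 0.27 and Evl, an actin regulator, at -0.72 ± 0.27. Set and phosphatase 2A genes had -0.49, -0.20 relative to all genes, with 31 of 31 lower (adjusted p = 0.023), with the regulatory subunits Ppp2r2d (-0.73 ± 0.26) and Ppp2r2c (-0.42 ± 0.18). Set itself is not among these members, since no cluster carried its symbol, and Setsip was not in the list. Both subunits were below the odorant receptor median on every wt_Set array. Histone acetylation genes had -0.42, -0.13 relative to all genes, with 29 of 30 lower (adjusted p = 0.0422), with the deacetylases Hdac2 (-0.91 ± 0.30) and Sirt6 (-0.71 ± 0.23). Below the median difference of all genes, rather than below mCherry, lay 68 of 83 respiratory chain, 43 of 46 splicing and 44 of 47 cytoskeleton genes. For Set and phosphatase 2A it was 25 of 31, and for histone acetylation 19 of 30. All 5 lists lay inside the central 95% of random lists of the same mean level, at percentiles 18.3 for respiratory chain, 35.2 for splicing, 76.5 for cytoskeleton, 20.2 for Set and phosphatase 2A and 21.6 for histone acetylation.

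The microglia and macrophage list had a median difference of 0.13 in wt_Set, 0.42 relative to all genes, with 11 of 14 members higher than in mCherry (adjusted p = 0.000266). Its members included C1qa, a complement component (0.62 ± 0.24), and the lysozyme gene Lyz2 (-0.52 ± 0.84). The photoreceptor and bipolar list, with 5 tested members, had 0.02, 0.30 relative to all genes (adjusted p = 0.0403), with cone transducin Gnat2 at 0.30 ± 0.15. The interferon list (adjusted p = 0.0405) and the NF-kB list (adjusted p = 0.0113) were called above other genes although their medians were below 0, at -0.10 and -0.13, or 0.19 and 0.16 relative to all genes. Of their members 8 of 20 and 10 of 24 were higher, among them Oas1a (0.78 ± 0.36), Oas1i (0.42 ± 0.19), the chemokine Ccl5 (0.48 ± 0.21) and Tnf (0.38 ± 0.22). Most members were lower, among them Psmb9, an immunoproteasome subunit (-0.40 ± 0.21), the transcription factor Irf9 (-0.35 ± 0.25), the growth factor Csf1 (-0.79 ± 0.64) and the NF-kB inhibitor Nfkbia (-0.50 ± 0.44). Gnat2 and Psmb9 were below the odorant receptor median on every wt_Set array. The 4 lists above other genes too were lost with an estimated correlation (adjusted p = 0.969 for each). Among random lists of the same mean level the microglia and NF-kB lists lay above the central 95%, at percentiles 99.9 and 99.7, and the interferon and photoreceptor lists inside it, at 94.3 and 79.3. Leaving out 1 array moved these member values by over 1.5 times: Lyz2 -0.78, Oas1i 0.27, Oas1a 0.31, Irf9 -0.13, Tnf 0.19, Csf1 -1.33 and Nfkbia -0.85 without mCherry replicate 1, Lyz2 -0.26, Tnf 0.58, Csf1 -0.25 and Nfkbia -0.11 without mCherry replicate 3, Lyz2 0.28, Psmb9 -0.22, Csf1 -0.40 and Nfkbia -0.28 without wt_Set replicate 1, Lyz2 -1.08 without wt_Set replicate 2, and Irf9 -0.21 without wt_Set replicate 3. Without mCherry replicate 1, where the microglia list's shift relative to all genes fell to 0.14, 3 of the 9 calls were kept (respiratory chain, microglia, photoreceptor). Without wt_Set replicate 3 it was 4 (respiratory chain, splicing, microglia, NF-kB), 8 without mCherry replicate 2, 7 without mCherry replicate 3, 8 without wt_Set replicate 1 and 7 without wt_Set replicate 2, and with cyclic loess 3 (splicing, microglia, NF-kB).

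**Figure D3:**
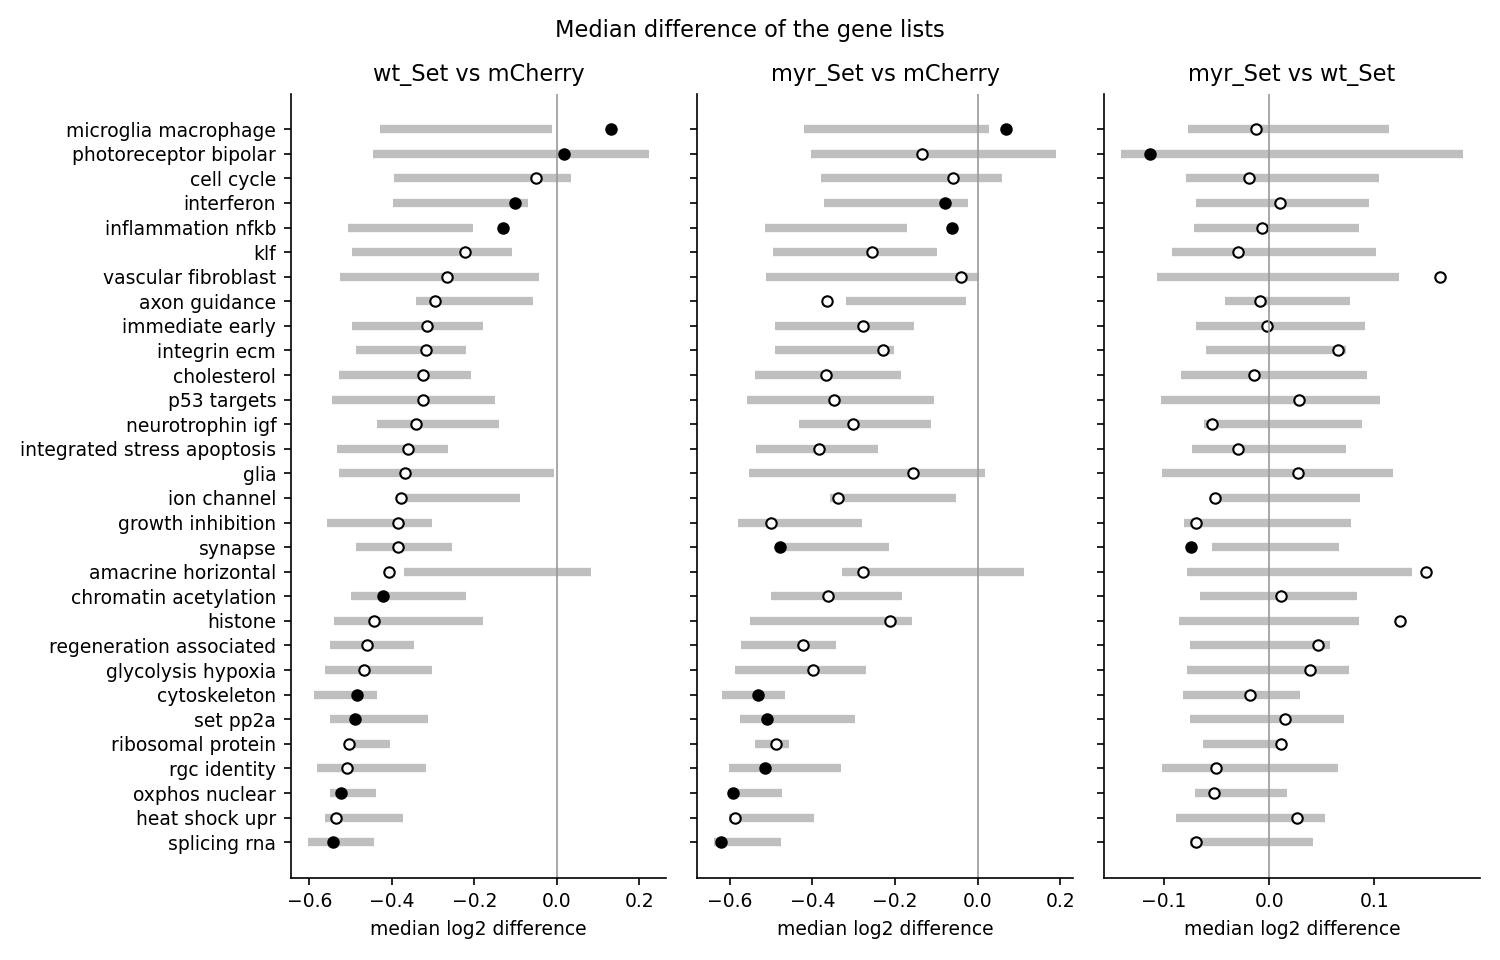
Median log2 difference of each gene list (x axis, with its own scale in the panel of myr_Set against wt_Set) for the 3 comparisons. Filled circles passed camera's adjusted p of 0.05, open circles did not, and grey bars hold the central 95% of 10000 random lists matched on mean level; the microglia list lay at percentile 99.9 of its random lists in wt_Set and 99 in myr_Set, and the respiratory chain list at 18.3 and 4.16.

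The comparison of myr_Set with mCherry asks what myr-Set-β alters. Rgs4, a regulator of G-protein signalling in neurons, was lower in myr_Set, with 8.48 ± 0.16 against 9.50 ± 0.29 in mCherry (SD, n = 3), as was Fabp3, with 8.33 ± 0.41 against 9.49 ± 0.07. Kcna2, an axonal potassium channel, had 7.12 ± 0.17 against 7.86 ± 0.16, and Tenm3, a teneurin that acts in visual wiring, 7.31 ± 0.25 against 8.48 ± 0.47 in cluster 17707774, while its other cluster differed by only -0.26 ± 0.25 (SE). Aifm1 (-0.64 ± 0.14) and Iftap (-1.59 ± 0.35) were also lower. Cx3cr1 (0.68 ± 0.19), RT1-O1 (7.27 ± 0.36 against 6.07 ± 0.39) and the odorant receptors Or52r1c (1.21 ± 0.23), Or52n4d (1.40 ± 0.37) and Or10ak7 (0.71 ± 0.20) were higher. Iftap was below the odorant receptor median on every myr_Set array, and Cx3cr1 and RT1-O1 on every mCherry array. In the cluster first given for each gene named so far in this comparison limma's adjusted p was 0.447. No cluster passed 0.05, the smallest value being 0.332.

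The rule also selected Emc9 (-0.75 ± 0.16), Rp9 (-0.99 ± 0.22), Dus2, a transfer RNA enzyme (-0.65 ± 0.16), rnf141 (-0.81 ± 0.20), Bend6 (-0.71 ± 0.17) and Chtopl1 (-0.95 ± 0.24) on the lower side. On the higher side it selected Or10al27 (1.18 ± 0.30), Or8h7b (0.79 ± 0.21), Apol3l1 (0.75 ± 0.20, and 0.43 ± 0.40 in its other cluster), Ldoc1 (0.51 ± 0.14), Ghrhr, the receptor of growth hormone releasing hormone (0.52 ± 0.15), Ucp3, a mitochondrial carrier (0.56 ± 0.17) and Upk2 (0.70 ± 0.21). Emc9 and rnf141 were below the odorant receptor median on every myr_Set array, and Ldoc1 on every mCherry array. At an unadjusted p under 0.05 there were 1796 clusters, 526 higher and 1270 lower, with 917 expected by chance. The share of higher clusters, 29.3%, was 56.8% with quantile normalization and 57.7% with cyclic loess. The arrays of myr_Set and mCherry did not overlap in 11.4% of clusters, against 10% by chance. The 1796 clusters became 741, 2729 and 994 without mCherry replicates 1, 2 and 3, and 642, 1033 and 6141 without myr_Set replicates 1, 2 and 3. They became 891 in a fit of only these 2 groups, 3801 with gene-by-gene and 8627 with planned array weights, and 2986 with no level filter, 842 with the filter at the 75th percentile and 1158 with single-symbol clusters only, which change the number tested.

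In myr_Set 9 lists passed camera, 6 below and 3 above the other genes. With an estimated correlation none passed (adjusted p = 0.969 for each), nor with fry (lowest adjusted p = 0.375), and 0 members passed when adjusted over the list alone. Respiratory chain genes had a median of -0.59, -0.33 relative to all genes, with 82 of 83 lower (adjusted p = 0.000159). Among them were Atp5mc1 of ATP synthase (9.62 ± 0.48 against 10.41 ± 0.06, SD, n = 3) and the assembly factor Ndufaf5 (-0.90 ± 0.31 SE). Splicing factors had -0.62, -0.36 relative to all genes, with 46 of 46 lower (adjusted p = 0.00161), including Tra2b (-1.13 ± 0.38) and Ddx39b (-0.89 ± 0.37). Cytoskeleton genes had -0.53, -0.27 relative to all genes, with 47 of 47 lower (adjusted p = 0.00161), with Tuba4a at -0.84 ± 0.27 and Evl at -0.70 ± 0.27. Synapse genes had -0.48, -0.22 relative to all genes, with 39 of 40 lower (adjusted p = 0.0113), with gephyrin, Gphn, the scaffold of inhibitory synapses, at -0.83 ± 0.26 and neuroligin Nlgn1 at -0.65 ± 0.21. Ganglion cell markers had -0.51, -0.25 relative to all genes, with 24 of 25 lower (adjusted p = 0.0337), including the transcription factors Pou4f3 (-0.60 ± 0.23) and Ebf3 (-0.67 ± 0.27). Their shift relative to all genes ran from -0.42 to -0.03 over the alternatives, and the call held in 11 of 18. Set and phosphatase 2A genes, again without Set itself, had -0.51, -0.25 relative to all genes, with 28 of 31 lower (adjusted p = 0.0418), with Ppp2r2d at -0.82 ± 0.26 and the nucleosome assembly gene Nap1l3 at -0.82 ± 0.27 (-0.36 ± 0.25 in its other cluster). Leaving out 1 array moved these member values by over 1.5 times: Pou4f3 -0.34 without mCherry replicate 1 and Nap1l3 -0.51, Evl -0.46, Tra2b -0.72 and Ddx39b -0.44 without myr_Set replicate 1. Pou4f3 and Nlgn1 were below the odorant receptor median on every myr_Set array. Below the median difference of all genes lay 74 of 83 respiratory chain, 44 of 46 splicing, 47 of 47 cytoskeleton and 31 of 40 synapse genes. For ganglion cell markers it was 22 of 25, and for Set and phosphatase 2A 23 of 31. All 6 lists lay inside the central 95% of random lists of the same mean level, at percentiles 4.16 for respiratory chain, 6 for splicing, 60.7 for cytoskeleton, 2.76 for synapse, 33.6 for ganglion cell markers and 18.6 for Set and phosphatase 2A.

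The microglia list had a median of 0.07 in myr_Set, 0.33 relative to all genes, with 10 of 14 higher (adjusted p = 0.00161), C1qa at 0.66 ± 0.24 and Lyz2 at -1.48 ± 0.84. The interferon (adjusted p = 0.0279) and NF-kB lists (adjusted p = 0.025) were called above other genes with medians below 0, at -0.08 and -0.06, or 0.18 and 0.20 relative to all genes. Of their members 9 of 20 and 10 of 24 were higher, among them Ifi47 (0.36 ± 0.18), Oas1i (0.33 ± 0.19), Nos2 (0.47 ± 0.18) and Tnf (0.51 ± 0.22). Most members were lower, among them Ifi27 (-0.64 ± 0.36), Irf9 (-0.35 ± 0.25), the chemokine Cxcl1 (-0.78 ± 0.71) and the cytokine Il6 (-0.66 ± 0.64). Ifi47 was below the odorant receptor median on every array of both groups. The 3 lists above other genes too were lost with an estimated correlation (adjusted p = 0.969 for each). Among random lists of the same mean level the microglia and NF-kB lists lay above the central 95%, at percentiles 99 and 99.8, and the interferon list inside it, at 90.5. Leaving out 1 array moved these member values by over 1.5 times: Lyz2 -0.63, Ifi47 0.23, Ifi27 -0.33, Irf9 -0.20, Cxcl1 0.10 and Il6 -0.022 without myr_Set replicate 1, Oas1i 0.18, Irf9 -0.13, Tnf 0.31 and Il6 -1.16 without mCherry replicate 1, Ifi27 -0.98, Cxcl1 -1.24 and Il6 -1.10 without myr_Set replicate 3, Cxcl1 -1.25 without mCherry replicate 2, Cxcl1 -0.31 and Il6 -0.09 without mCherry replicate 3, and Cxcl1 -1.19 without myr_Set replicate 2. Without mCherry replicate 1, where the microglia list's shift relative to all genes fell to 0.14, 3 of the 9 calls were kept (respiratory chain, splicing, microglia). Without myr_Set replicate 1, 2 or 3 in turn it was 7, 8 and 6, and with cyclic loess 4 (splicing, microglia, interferon, NF-kB).

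The comparison of myr_Set with wt_Set asks whether the forms of Set-β differ. The Set pseudogene Setl2 (0.80 ± 0.21 SE) and Tdg, a thymine DNA glycosylase (0.60 ± 0.18), were higher in myr_Set, and Tmem258l2 was lower (-0.63 ± 0.19). For each of these genes limma's adjusted p was 0.9998, the smallest value in this comparison. The neuropeptide gene Gal had 9.04 ± 0.69 in myr_Set and 8.16 ± 0.49 in wt_Set (SD, n = 3), and the stress gene Ddit4 had 7.46 ± 0.20 and 8.07 ± 0.38. Synapse genes had a median of -0.07, -0.09 relative to all genes, with 29 of 40 lower (camera's adjusted p = 0.0403), including Gphn (-0.50 ± 0.26) and synaptophysin, Syp (-0.54 ± 0.33). Leaving out 1 array moved these differences, 0.88 ± 0.40 for Gal and -0.61 ± 0.23 for Ddit4 with all arrays, by over 1.5 times (Gal 0.51 without myr_Set replicate 3, Gphn -0.24 and Syp -0.24 without myr_Set replicate 1, and Ddit4 -0.40 without wt_Set replicate 3). The 5 photoreceptor and bipolar genes had -0.11, -0.13 relative to all genes (adjusted p = 0.0337), with Gnat2 at -0.44 ± 0.15. Gnat2 was below the odorant receptor median on every array of both groups, and Tdg on every wt_Set array. Among random lists of the same mean level the synapse list lay at percentile 0.45, below the central 95%, and the photoreceptor list at 5.72, inside it. Above it, without passing camera, lay histones (0.12, percentile 99.8), endothelial, mural and fibroblast markers (0.16, percentile 99.5), amacrine and horizontal markers (0.15, percentile 98.5) and ribosomal proteins (0.01, percentile 98.3). With an estimated correlation neither the synapse nor the photoreceptor list passed (adjusted p = 0.969 for each), nor with fry (lowest adjusted p = 0.375), and 0 members passed when adjusted over the list alone.

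No cluster passed limma's adjusted p of 0.05 between the forms of Set, and 208 had an unadjusted p under 0.05, 104 higher and 104 lower, with 917 expected by chance. Without myr_Set replicate 1 there were 833 and without myr_Set replicate 3 there were 590. There were 1055 with gene-by-gene and 4514 with planned array weights, and 749 with no level filter, 70 with the filter at the 75th percentile and 52 with single-symbol clusters only, which change the number tested. The arrays did not overlap in 4.39% of clusters, against 10% by chance. Neither list call held without wt_Set replicate 1, myr_Set replicate 2 or myr_Set replicate 3, and 1 of the 2 held without mCherry replicate 1, wt_Set replicate 2, wt_Set replicate 3 or myr_Set replicate 1.

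Across the 18343 tested clusters the differences of wt_Set and myr_Set from mCherry correlated with r = 0.84 and had the same sign in 87.5%. This correlation is across genes, which are not independent replicates, and both comparisons share the mCherry arrays. The share of equal signs was not set against a value for unchanged groups, and shared controls raise it too. Simulated independent noise against shared controls gave r = 0.50, and 100 resamplings of the arrays' own deviations gave a median of 0.60 and a 95th percentile of 0.89, above the observed value. The covariance was 0.16, against 0.0674 for independent noise, a difference of 0.093, and a 95th percentile of 0.162 over the resamplings. Much of this rested on myr_Set replicate 1, without which r was 0.59 and the covariance 0.0851, against 0.44 and 0.0514 for independent noise, a resampled median r of 0.47 and a resampled 95th percentile of the covariance of 0.125 with the same arrays. The covariance was above its resampled 95th percentile without mCherry replicate 2 (0.249 against 0.227) and without myr_Set replicate 3 (0.232 against 0.126), and below it without any other single array. The 3 control arrays cannot be split into parts of 2, and part of the excess may come from the shared controls.

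Markers of mural cells differed between replicate 1 and replicates 2 and 3. Tagln, a smooth muscle actin-binding protein, had 7.93, 7.34 and 6.7 in replicate 1 of mCherry, wt_Set and myr_Set, and 11.9 to 12.6 in replicates 2 and 3. Group levels of Tagln were 10.98 ± 2.65 (SD, n = 3), 10.37 ± 2.63 and 10.43 ± 3.25, and those of Vim, an intermediate filament of glia and mesenchymal cells, 10.77 ± 1.90, 10.26 ± 2.12 and 10.61 ± 1.95. The most abundant microglial marker Fcer1g had 8.61 ± 0.42 in mCherry, 8.73 ± 0.56 in wt_Set and 9.02 ± 0.79 in myr_Set. The amacrine marker Slc6a9 had 8.15 ± 0.41, 7.74 ± 0.17 and 7.69 ± 0.09. Isx, the most abundant tested gene of the photoreceptor and bipolar list, had 7.12 ± 0.22, 7.49 ± 0.12 and 7.49 ± 0.64. These levels are close to the odorant receptor median and do not show RNA of bipolar cells. With a term for replicate 1, 0 clusters passed limma's adjusted p of 0.05 in the 3 comparisons, with 1989, 1855 and 221 at an unadjusted p under 0.05, and 8 of 9, 9 of 9 and 2 of 2 list calls were kept. Replicates 2 and 3 alone also gave 0 clusters, with 1718, 494 and 807 at an unadjusted p under 0.05, and kept 6, 3 and 1 list calls. Replicate 1 alone holds 1 array per group and allows no test.

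**Figure D4:**
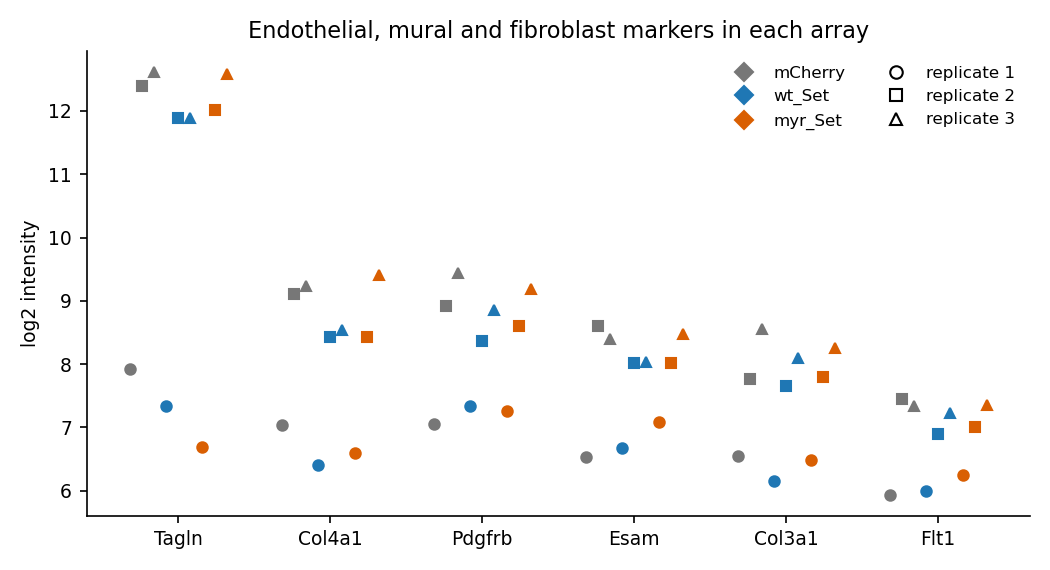
Log2 intensity (y axis) of endothelial, mural and fibroblast markers (x axis) in each of the 9 arrays, coloured by group with symbols for the replicate number. For Tagln, replicate 1 lay between 6.7 and 7.93 and the other arrays between 11.9 and 12.6.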

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

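Cyclic loess, gene-by-gene array weights, the replicate 1 term and replicates 2 and 3 alone were chosen after seeing the data. The planned array weights did not converge (weight 165 for myr_Set replicate 2, 0.151 for replicate 1). With them 5903 clusters passed adjusted p 0.05 in myr_Set against mCherry and 1270 in myr_Set against wt_Set, and Setsip in myr_Set had -0.76 with a limma adjusted p of 0.00874; every other setting run, gene-by-gene weights included, gave 0 clusters in the 3 comparisons. The number of lists past camera's threshold in wt_Set and myr_Set against mCherry and in myr_Set against wt_Set (9, 9 and 2) was 0 in each with an estimated correlation and with fry. It was 15, 16 and 1 with no level filter, 3, 4 and 3 with cyclic loess, and 8, 5 and 7 with replicates 2 and 3 alone. Between the forms of Set it was 1 with trend and robust settings and 5 with the replicate 1 term. Over the omission of single arrays the list counts ran from 5 to 11, from 5 to 12 and from 1 to 10. Without mCherry replicate 1 they were 5, 5 and 1, and between the forms of Set 4 and 1 without wt_Set replicates 1 and 2, and 10, 1 and 5 without myr_Set replicate 1, 2 or 3 in turn. The cause was not tested. Omitting single arrays gave Setsip differences of -0.77 to -0.59 in wt_Set and -1.09 to -0.41 in myr_Set against mCherry. Between the forms of Set the Setsip difference ran from -0.44 to 0.25, turning sign without wt_Set replicate 1 or myr_Set replicate 1, and was 0.37 in replicates 2 and 3. That of Lyz2 in wt_Set against mCherry ran from -1.08 to 0.28, turning sign without wt_Set replicate 1, and was 0.0149 in replicates 2 and 3. In myr_Set against mCherry, Cxcl1 ran from -1.25 without mCherry replicate 2 to 0.10 without myr_Set replicate 1, the omission that turned its sign, and was 0.11 in replicates 2 and 3, where Irf9 had 0.0172. The planned array weights brought 46 values of named genes past the threshold, and 2155 values under the alternatives kept direction and side. Camera gives the direction of a list, while the medians of the NF-kB, cytoskeleton, synapse and photoreceptor lists relative to all genes changed sign under some settings. In myr_Set against mCherry they ran from -0.08 to 0.42 for NF-kB, -0.45 to 0.004 for cytoskeleton and -0.35 to 0.004 for synapse genes. NF-kB genes in wt_Set against mCherry ran from -0.06 to 0.49. Between the forms of Set the range was -0.15 to 0.009 for synapse genes and -0.44 to 0.13 for photoreceptor genes.

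A replicate block was run because the labels share numbers. Same-numbered arrays had deviations correlated from -0.069 to 0.383 over 9 pairs, 5 of them over 0.1, and 5 of 9 arrays were closest to their own number. The numbers were therefore not taken as pairs, since not every pair was over 0.1, although replicate 1 of all groups shared the difference from replicates 2 and 3 in 150 clusters. With the block 0 clusters passed in the 3 comparisons, and 9, 9 and 4 lists were called. These included 7 of the 9 calls in wt_Set (histone acetylation and interferon not), 7 of the 9 in myr_Set (Set with phosphatase 2A and NF-kB not) and 2 of the 2 between the forms of Set.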

Other observations

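The tests of the 5 microglial markers, of the order of replicate 1, of the cluster counts at adjusted p 0.05 and of the cluster count of replicate 1 were chosen after the result was seen, as were the comparisons of replicate 1 and of odorant receptors, the level-matched lists, cyclic loess, the replicate 1 term and replicates 2 and 3 alone.

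Replicate 1 differed from replicates 2 and 3 over all 3 groups. In a limma fit with group in the model, 150 clusters passed adjusted p 0.05, 148 of them lower in replicate 1. In most of the genes named here the signal of replicate 1 was at or below the median of odorant receptors on the same array in 1 or more of the 3 groups, so that only a bound on the fold is given, with replicate 1 raised to that median. Sparc, a matrix-binding glycoprotein, was at least 26.3-fold higher in replicates 2 and 3 (adjusted p = 0.00013), Tagln at least 24-fold, Myl9, a myosin light chain, at least 14.8-fold, Cald1, caldesmon, at least 12-fold, Fn1, fibronectin, at least 10.6-fold and Bgn, a matrix proteoglycan, at least 7.62-fold, while Vim, above that median on every array, was 10.6-fold higher. The endothelial, mural and fibroblast list had a median difference of -1.37, with 10 of 11 members lower in replicate 1. This median, without a bound, is the value of Col1a2. Its members Pdgfrb, Col4a1, Esam and Col3a1 were at least 2.91-fold, at least 2.84-fold, at least 1.98-fold and at least 1.68-fold higher in replicates 2 and 3, and Cspg4 at least 2.07-fold. With the same bound Col1a2 had 1.18-fold, Col1a1 1.05-fold, Flt1 0.96-fold, Rgs5 0.89-fold and Cdh5 0.66-fold, so that the bound leaves no clear fall for these members. Without the bound Flt1 was 2.22-fold higher in replicates 2 and 3 and passed the threshold (limma adjusted p = 0.0253). Unbounded values of the others, none past it, were 2.59-fold for Col1a2, 1.43-fold for Rgs5, 1.06-fold for Col1a1 and 0.90-fold for Cdh5. Ganglion cell markers had a median of 0.07 and synapse genes 0.13, while NF-kB genes had -0.63, integrins and matrix -0.63, ribosomal proteins -0.57, heat shock and unfolded protein response genes -0.54, glycolysis and hypoxia genes -0.39 and microglial markers -0.36. Respiratory chain genes had -0.36, with 75 of 83 lower in replicate 1, and splicing factors -0.22, with 35 of 46.

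Lists that did not pass camera in wt_Set and myr_Set against mCherry are given with both median differences, next to all-gene medians of -0.29 and -0.26. Regeneration-associated genes had -0.46 and -0.42, with the transcription factors Sox11 at -0.64 ± 0.28 (SE) in wt_Set (Sox11 -0.42 without mCherry replicate 1 and Sox11 -0.42 without wt_Set replicate 3) and Klf6 at -0.52 ± 0.22 in myr_Set (Klf6 -0.35 without myr_Set replicate 1), and Krüppel-like factors had -0.22 and -0.25. Sox11 was below the odorant receptor median on every wt_Set array. Axon guidance genes had -0.29 and -0.37, growth inhibition genes -0.39 and -0.50, growth factor signalling genes -0.34 and -0.30, integrins and matrix -0.32 and -0.23, and voltage-gated channels -0.38 and -0.34. Stress and apoptosis genes had -0.36 and -0.39, with Ddit3, the transcription factor CHOP, at -0.96 ± 0.29 in myr_Set. The p53 targets had -0.32 and -0.35, and heat shock and unfolded protein response genes -0.53 and -0.59, with the chaperone Dnajb11 at -0.93 ± 0.38 in wt_Set. Sterol synthesis genes had -0.32 and -0.37, with Fdps, a prenyl synthase, at -1.34 ± 0.37 in wt_Set, and glycolysis and hypoxia genes -0.47 and -0.40. Immediate early genes had -0.32 and -0.28, cell cycle genes -0.05 and -0.06, ribosomal proteins -0.50 and -0.49, and histones -0.44 and -0.21. Glial markers had -0.37 and -0.16, amacrine and horizontal markers -0.41 and -0.28, and endothelial, mural and fibroblast markers -0.27 and -0.04. In wt_Set, synapse genes had -0.39 and ganglion cell markers -0.51, and in myr_Set histone acetylation genes had -0.36 and photoreceptor markers -0.14. Among random lists of the same mean level, of which 5% lie outside the central 95% by chance, lists below it were amacrine and horizontal markers and ribosomal proteins in wt_Set, at percentiles 1.03 and 1.43, and axon guidance in myr_Set, at 0.385. The other lists of this paragraph lay inside it.

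Odorant receptors, which the rule for named genes did not exclude under their newer names, were looked at as a family after their values were seen. Of 255 tested genes, 209 were higher in wt_Set and 213 in myr_Set than in mCherry, with medians of 0.25 and 0.22, 0.35 and 0.39 with quantile normalization, and 0.36 and 0.34 with cyclic loess. Only receptors past the level filter were counted. The filter uses the mean over all arrays, most of them of the Set groups, which favours receptors that are high there. These counts are therefore no test of a change in the family. In replicates 2 and 3 alone the medians were 0.13 and -0.00521. Their median log2 intensity was 6.81, 7.30 and 7.09 in the mCherry arrays, 6.93 in myr_Set replicate 3, and 7.29 to 7.61 in the other Set arrays.

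The respiratory chain list lay below other genes in both Set groups by camera at its preset correlation, and with an estimated correlation both calls were lost (adjusted p = 0.969 and 0.969). A narrower signal range may give this. Among random lists of the same mean level its median lay at percentile 18.3 in wt_Set and 4.16 in myr_Set, inside the central 95%. Cyclic loess, chosen after seeing the data, ended both of camera's calls (adjusted p = 0.0944 and 0.0944). The shift relative to all genes then went from -0.24 and -0.33 to -0.08 and -0.08. Each call held in 15 of 18 alternatives, among them quantile normalization, which was fixed beforehand and gives all arrays the same distribution. With it the most abundant decile of clusters still had -0.11 in wt_Set and -0.18 in myr_Set against mCherry. The narrowest array, myr_Set replicate 1, was not the whole cause in myr_Set, since the call held without it (adjusted p = 0.00395, with 1.16e-06 to 0.969 over the alternatives), although the shift became -0.11, and in wt_Set it became -0.13 without mCherry replicate 3. The list was also lower in replicate 1 of the groups together, and in replicates 2 and 3 alone, where both calls held, the shift was -0.20 in wt_Set and -0.14 in myr_Set. An effect of Set-β on these genes stays open and was not separated from signal range by these tests.

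The microglia and macrophage list lay above other genes in both Set groups by camera at its preset correlation, and with an estimated correlation both calls were lost (adjusted p = 0.969 and 0.969). Its median lay above most level-matched lists, at percentiles 99.9 in wt_Set and 99 in myr_Set. Those lists drew genes independently, so they cannot exclude a movement that correlated genes share. Odorant receptors of similar mean level (7.34 against 7.49) had medians of 0.25 and 0.22, above those of the microglia list. Without mCherry replicate 1, the control array with the lowest odorant receptor signal, camera's calls held at the preset correlation. Adjusted p was 0.0145 in wt_Set (1.84e-06 to 0.969 over the alternatives) and 0.0496 in myr_Set (1.50e-05 to 0.969). The shift relative to all genes went from 0.42 and 0.33 to 0.14 and 0.14, so how much rests on this array stays open. A prediction about this array was dropped after its result was known. In wt_Set the shift went to 0.28 without wt_Set replicate 2. Background signal of probes for genes that ganglion cells are not known to express is a candidate explanation. Against random lists of odorant receptors the median lay at percentile 6.99 in wt_Set, inside the central 95%, and at 1.84 in myr_Set, below it; the bound, written once receptors had been seen among the named genes, was two-sided and did not foresee a lower position, so that background stays open there. More RNA of microglia stays open too. The 5 most abundant markers (Fcer1g, Tyrobp, Cd14, Cd68 and C1qa) had a mean difference of 0.252 ± 0.343 in wt_Set (SE, exact permutation p = 0.6, two-sided, n = 3). This test did not pair arrays by replicate number. Microglial markers had a median of -0.36 in replicate 1 against replicates 2 and 3, which adds to its spread. Immunopanning is meant to leave such cells out, but how far it did so was not measured.

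The endothelial, mural and fibroblast list had a lower median in replicate 1 of each group, although not every member fell once bounded by the odorant receptor median. A chance order of the arrays gave as low a sum in 1 of 27 ways to pick 1 array per group (exact one-sided p = 0.037, the smallest possible). This test was chosen once replicate 1 had been seen to be lowest in each group, so its result was fixed and adds nothing. Of the 27 picks, 1, the real one, gave 150 clusters or more, the highest other giving 0. The central 95% of random lists of the same level ran from -0.26 to 0.10, and the list lay at percentile 0, so that a general shift of dim or bright genes does not account for it. The genes of these random lists were drawn independently, so the range may be too narrow for correlated genes. A candidate explanation is a different share of mural cells or fibroblasts in the preparation used for replicate 1. Immunopanning is meant to leave such cells out, while sorting took fluorescent cells, which need not be ganglion cells. In replicates 2 and 3 Tagln, at 11.9 to 12.6, lay above the ganglion cell marker Stmn2, at 10.6 to 11.8. Intensities of different clusters also depend on their probes, so this does not rank the amounts of their RNA. Cspg4 is also in the glial list, and no biological explanation was tested.

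For the group comparisons, 6 arrays make 10 splits of 3 against 3, too few for a share under 0.05. At adjusted p 0.05 the real split and the highest other gave 0 clusters in all 3 comparisons, so that 10 of 10 splits gave as many. At unadjusted p under 0.05, wt_Set against mCherry gave 1865 clusters and the highest other split 894 (1 split as large, the real one). For myr_Set against mCherry these were 1796 and 6544 (2 splits as large, the real one included). The split with 6544 set mCherry replicates 1 and 3 and myr_Set replicate 3, the arrays of widest signal range, against the rest, which points to a structure of the samples. For myr_Set against wt_Set they were 208 and 1592 (9 splits as large, the real one included).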
